A study of Mus musculus with 32 samples.

How the data were processed

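RNA of mouse C2C12 cells was measured on 32 Affymetrix arrays of 1 design. The TSA arm had 20 arrays of control and TSA-treated cells at 0, 4, 12, 24 and 48 h (n = 2 per group), and the Sir2 arm had 12 arrays of vector and Sir2 cells at 12 and 36 h (n = 3 per group). Arrays were grouped by treatment and time as the labels give them, and the dose of TSA and whether it was washed out are not stated there. The deposited values were intensities, 1 per probe set and array, on a linear scale. Per the labels, those of the Sir2 arm were signal intensities from MAS5, with no version stated. The tool of the TSA arm is not given in the sources used here. Its deposited intensities include values below 0, which do not occur in MAS5 signal and do occur in the older average difference measure. Each array had been scaled to a common trimmed mean within its arm before deposit, as the values show.

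Of 12488 probe sets, 66 Affymetrix controls were left out, which left 12422. Of these 10833 mapped to 1 gene symbol, 396 to several and 1193 to none, and 10817 symbols were updated through their Entrez identifier, which gave 8251 genes. The groups, comparisons, filter, thresholds, gene lists and rule for naming genes were fixed before the data were examined. The plan was to add the 20th percentile of an arm's values before taking log2. In the Sir2 arm this was 8.82. In the TSA arm it was -13.7, which cannot be used, so values below 0 were set to 0 and the 40th percentile, 137.7, was added. Changes of dim probe sets are therefore compressed in both arms. A group at or below 0 on every array is left without spread, so p can be too small and no fold is given. Probe sets with a mean at or above the 40th percentile of the arm's probe set means (144.9 and 31.1) were tested, 7453 in each arm, of which 6633 were shared.

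Each arm was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, lmFit and eBayes (10 and 8 residual degrees of freedom, prior 2.45 and 3.93). Adjusted p values are Benjamini-Hochberg values within a comparison, and a probe set passed under 0.05. The comparisons were TSA against control at each time, their mean, and an F test of whether the effect differed between times; control cells at each time against 0 h and across the series; and in the Sir2 arm Sir2 against vector at each time, their mean, the difference of these effects, and vector 36 h against 12 h. Values after ± are standard errors for log2 changes and standard deviations for intensities. Quality measures were compared by exact permutation of the treatment labels within times. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.

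There were 32 gene lists, fixed in advance, with 749 genes, of which 640 were on the array. They covered the sarcomere, myogenic factors, inhibitors of differentiation, muscle metabolism, excitation-contraction coupling, fusion and adhesion, DNA replication, mitosis, cell cycle exit, the TGF-beta family, the insulin-like growth factor axis, extracellular matrix, deacetylases, the deacetylase inhibitor response, p53 targets, fatty acid oxidation, oxidative phosphorylation, glycolysis, sterol and lipid synthesis, the endoplasmic reticulum stress and amino acid response, heat shock, oxidative stress, immediate early genes, ribosome biogenesis, the interferon response and antigen presentation, inflammatory cytokines, and markers of smooth muscle, adipocytes, bone and cartilage, neurons, leukocytes and endothelium. Lists were tested with camera of limma, on 1 probe set per gene, with the preset correlation of 0.01 and again with a correlation estimated from the residuals, and adjusted over the lists of a comparison. Genes that passed in 1 arm also served as lists in the other.

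Genes were named by rule: Sirt1, 18 fixed genes of muscle and cell cycle control, the genes of largest log2 change past the threshold with non-overlapping groups or the same sign at every time (8 per direction for the means, Sir2 at 36 h and the changes of untreated cells, 4 per direction for each time of TSA), up to 4 members of smallest p of a list, and the 5 genes of smallest p where an effect changed with time. Not every gene of the rule is printed. The fit was tested on known changes in simulated independent noise. At a log2 change of 1 it recovered 53.7% to 65.7% of the changed probe sets at single times of the TSA arm, 98.5% for the TSA mean, 85.1% to 86.6% at single times of the Sir2 arm and 97.0% for the Sir2 mean, and 3 to 12 of 7223 unchanged probe sets were called. At a log2 change of 0.5 the TSA arm recovered 1.49% to 13.4% at single times, so small changes there were mostly missed.

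The alternatives tried were quantile normalization, median centring, other pseudocounts, no filter and a 60th percentile filter, trend and robust variance estimation, replicate numbers as a block, a covariate for titles with the suffix b, fits of only the groups compared, an estimated correlation for lists, and leaving out each array. Added after the data were seen were further pseudocounts for the TSA arm, a floor with no pseudocount, fits without probe sets at or below 0 on most arrays, fits without the 2 arrays of 12 h in the Sir2 arm that deviate together, differences within arrays with and without the suffix b, and list tests between the ends of the TSA series and within treated cells.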

Results

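Mouse C2C12 cells, a line of skeletal myoblasts that leaves the cell cycle and forms myotubes when moved from growth medium to differentiation medium, were profiled on 32 Affymetrix arrays in 2 separate arms. The first arm followed untreated control cells and cells treated with trichostatin A (TSA), an inhibitor of the zinc-dependent histone deacetylases, in growth medium (0 h) and after 4, 12, 24 and 48 h in differentiation medium, with 2 arrays per group and 20 in all. The second arm compared cells carrying the empty pHan vector with cells carrying pHan with Sir2, the NAD-dependent deacetylase whose mouse counterpart is Sirt1, after 12 and 36 h in differentiation medium, with 3 arrays per group and 12 in all. The number of arrays limits the precision of every value, and nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples. Levels are not compared between the arms, which were scaled separately. Log2 changes were taken after adding a pseudocount (137.7 in the TSA arm and 8.82 in the Sir2 arm), so those of a gene with a group near or under it are compressed: they are smaller in size than the log2 ratio of its intensities and depend on the pseudocount. Medians are those of the log2 changes of a list, and a list that passed is given a second adjusted p where the call was lost with an estimated correlation between its genes.

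The arrays of each arm were even in scale. In the TSA arm the trimmed mean intensity lay between 800.57 and 800.69, the median between 253 and 286, and 21.1% to 24.2% of the values of an array were at or below 0. In the Sir2 arm the trimmed mean was 150.1 on every array, the median lay between 50.4 and 57.5, and every value was above 0. The Spearman correlation of an array with the rest of its group was 0.913 to 0.968 in the TSA arm and 0.967 to 0.972 in the Sir2 arm. Of 10 exact permutation tests of scale and RNA quality between treatments, stratified by time and two-sided, the smallest p was that of the ratio of 3' to 5' Gapdh signal in the TSA arm, a measure of RNA integrity, which was 0.815 ± 0.0438 with TSA and 0.866 ± 0.0415 in control (n = 10 each, exact p = 0.00823, Benjamini-Hochberg adjusted p = 0.0823). The adjusted p of the other tests was 0.233 or more.

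Untreated cells turned on the contractile programme and turned off division between 0 and 48 h, the comparison that shows what differentiation did without TSA (n = 2 each). Acta1, skeletal muscle actin, reached 19984 ± 91.9 against 61.4 ± 73.5, log2 change 6.71 ± 0.27, adjusted p = 1.97e-09. The myosin light chain Myl1 reached 24639 ± 3026 against 6.93 ± 4.84, log2 change 7.42 ± 0.29, adjusted p = 1.97e-09. The slow troponin C gene Tnnc1 reached 22699 ± 1773 against 49.1 ± 63.6, log2 change 6.97 ± 0.26, adjusted p = 1.21e-09. Mybph, a myosin-binding protein, reached 19599.6 ± 749.6 against 181 ± 43.4, log2 change 5.96 ± 0.14, adjusted p = 2.07e-11. Myog, the transcription factor myogenin, stood at 20101 ± 2002 against 71.2 ± 158 (adjusted p = 1.94e-07). Actc1 (cardiac actin, 15551 ± 989 against -48.99 ± 1.05, adjusted p = 3.12e-09), Igf2 (insulin-like growth factor 2, 16117 ± 1529.8 against -884 ± 115, adjusted p = 1.70e-10) and Cox6a2 (a muscle cytochrome oxidase subunit, 11691 ± 641 against -104 ± 72.02, adjusted p = 6.35e-14) were at or below 0 on both arrays of 0 h. No fold is given, and p can be too small. Myod1 rose by 1.37 ± 0.11 on the log2 scale (adjusted p = 7.67e-07), Mef2c by 1.56 ± 0.33 (0.00248), and the cell cycle inhibitor Cdkn1a by 3.03 ± 0.18 (8.59e-08).

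Genes of division fell over the same interval. Cdk1, the kinase that drives mitosis, had 78.7 ± 57.8 against 5755 ± 940.2, log2 change -4.78 ± 0.17, adjusted p = 9.15e-10. Anln, a cytokinesis protein, had a log2 change of -3.88 ± 0.14, adjusted p = 1.10e-09, the condensin gene Smc2 -3.74 ± 0.17, adjusted p = 5.12e-09, and Rrm1, a ribonucleotide reductase subunit, -4.52 ± 0.31, adjusted p = 3.06e-07. Id2, an inhibitor of myogenic helix-loop-helix factors, changed by -4.42 ± 0.25, adjusted p = 5.78e-08, Id1 by -2.29 ± 0.25, adjusted p = 1.59e-05, Id3 by -3.01 ± 0.34, adjusted p = 2.07e-05, and the cyclin gene Ccnd1 by -2.18 ± 0.23, adjusted p = 1.14e-05. Dnmt1 (-344 ± 177 against 2226 ± 122, adjusted p = 1.73e-08), Kif20a (-92.7 ± 122 against 1832 ± 64.9, adjusted p = 4.72e-10) and Racgap1 (-188 ± 98.3 against 1794 ± 63.5, adjusted p = 1.53e-04) were listed at or below 0 on both arrays of 48 h. In all, 2630 of 7453 probe sets passed at 48 h (1193 higher, 1437 lower), 153 at 4 h, 390 at 12 h and 959 at 24 h, each against 0 h, and 2980 differed across the control series. With only the arrays of 0 and 48 h in the fit, 1536 passed.

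Of 26 measured sarcomere genes, 20 rose, 0 fell and 6 did not pass (20 and 1 adjusted over the list alone), with median 2.81, adjusted p = 6.40e-16. Examples are Mylpf (4.03 ± 0.14) and Myl4 (5.03 ± 0.18). Muscle metabolic enzymes (13 measured) followed: 10 higher and 1 lower (10 and 1 adjusted over the list alone), median 1.03, adjusted p = 2.66e-05. The list of excitation-contraction coupling held 17 measured genes, of which 9 rose and 0 fell (9 and 0 adjusted over the list alone), median 1.25, adjusted p = 2.59e-05. The calcium pump gene Atp2a1 gained 4.76 ± 0.21 and the acetylcholine receptor gene Chrng 4.95 ± 0.23. Among 37 mitosis genes 36 fell and 0 rose (37 and 0 adjusted over the list alone), median -2.68, adjusted p = 1.27e-28. The DNA replication list behaved alike, with 31 lower and 1 higher (32 and 1 adjusted over the list alone) among 35 members, median -1.80, adjusted p = 8.74e-17, Pcna changing by -2.43 ± 0.14 and Uhrf1 by -2.77 ± 0.19. The endoplasmic reticulum stress and amino acid response (21 genes) had 13 higher and 1 lower (13 and 1 adjusted over the list alone), median 1.01, adjusted p = 2.11e-06. Slc3a2 changed by 1.77 ± 0.11, Herpud1 by 1.87 ± 0.14 and Ddit3 by 3.57 ± 0.34.

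Other lists passed in control cells with the preset correlation alone. Sterol and lipid synthesis had 19 members, of which 11 fell and 1 rose (12 and 2 adjusted over the list alone), median -0.79, adjusted p = 3.15e-04, and adjusted p = 0.129 with an estimated correlation. Idi1 changed by -2.01 ± 0.13 and Lss by -2.62 ± 0.21. Of 21 oxidative stress genes 11 fell and 1 rose (11 and 1 adjusted over the list alone), median -0.64, adjusted p = 0.00107, and adjusted p = 0.0528 with an estimated correlation. Gclm changed by -1.91 ± 0.14 and Mt2 by -1.70 ± 0.17. Myogenic factors (13 measured) had 5 higher and 1 lower (6 and 1 adjusted over the list alone), median 0.55, adjusted p = 0.0116, and adjusted p = 0.0890 with an estimated correlation. Of 15 genes of fusion and adhesion 7 rose and 1 fell (7 and 1 adjusted over the list alone), median 0.17, adjusted p = 0.0231, and adjusted p = 0.0886 with an estimated correlation. The tetraspanin Cd82 changed by 2.15 ± 0.13 and the cadherin Cdh15 by 1.77 ± 0.12. Without control 48 h replicate 1 the adjusted p was 0.0501.

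In growth medium, before differentiation began, TSA-treated cells had lower levels of every measured mitosis gene than control cells (n = 2 each, a comparison of what TSA did to cycling myoblasts). Of 37 such genes 0 rose, 37 fell and 0 did not pass (0 and 37 adjusted over the list alone), median -1.62, adjusted p = 1.16e-34. Cdc20, which triggers anaphase, had 1656 ± 218 against 10253 ± 23.3, log2 change -2.54 ± 0.16, adjusted p = 1.87e-06. The cyclin gene Ccnb2 had a log2 change of -2.14 ± 0.15, adjusted p = 2.46e-06, the tubulin-binding protein gene Stmn1 -1.88 ± 0.12, adjusted p = 1.95e-06 and Anln -1.94 ± 0.14, adjusted p = 2.96e-06. Kif23, a cytokinesis motor, was among the lower genes of largest change (358 ± 183 against 2693 ± 36.3, log2 change -2.57 ± 0.51, adjusted p = 0.00356). DNA replication genes moved the same way: of 35, 15 fell and 0 rose (22 and 0 adjusted over the list alone), median -0.56, adjusted p = 5.34e-08. Rfc4 changed by -1.15 ± 0.19, Pola1 by -0.92 ± 0.16 and Lig1 by -2.09 ± 0.37. Sterol and lipid synthesis fell too, with 13 lower and 0 higher (13 and 0 adjusted over the list alone) of 19, median -0.77, adjusted p = 4.05e-09. The isomerase gene Idi1 changed by -1.41 ± 0.13 and the synthase gene Hmgcs1 by -1.52 ± 0.16.

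Chchd10, a mitochondrial protein, rose with TSA at 0 h (2765 ± 307 against 175 ± 261, log2 change 3.47 ± 0.51, adjusted p = 4.74e-04). Sprr1a, a cornified envelope protein, had 1708 ± 262 against 4.003 ± 113, log2 change 3.39 ± 0.50, adjusted p = 4.88e-04. Pfn2, an actin-binding profilin, had 1436 ± 136 against 21.1 ± 61.8, log2 change 3.23 ± 0.21, adjusted p = 1.87e-06. The mean control levels of these genes lay within 1 standard deviation of 0, so their log2 changes are not ranked. Fst, which encodes the secreted myostatin antagonist follistatin, had 438 ± 7.67 against 59.9 ± 10.2, log2 change 1.54 ± 0.19, adjusted p = 1.31e-04. Myf5 (0.97 ± 0.18, adjusted p = 0.00188) and Cdkn1c (1.15 ± 0.21, adjusted p = 0.00222) rose. Myog stood at 709 ± 141 against 71.2 ± 158 (adjusted p = 0.00616). The call of Myog in TSA against control at 0 h was lost without TSA replicate 1 (adjusted p = 0.0561) or control replicate 1 (0.0830). Of 9 genes known to respond to deacetylase inhibitors in other cells 5 rose and 0 fell (6 and 1 adjusted over the list alone), median 0.74, adjusted p = 0.00396, and adjusted p = 0.0902 with an estimated correlation. The matricellular gene Ccn2 changed by 2.77 ± 0.21, Clu by 1.51 ± 0.21 and Gsn by 0.93 ± 0.12. Antigen presentation and interferon genes (12) had 4 higher and 0 lower (4 and 0 adjusted over the list alone), median 0.32, adjusted p = 0.0171, and adjusted p = 0.0902 with an estimated correlation. The histocompatibility gene H2-D1 changed by 1.68 ± 0.11 and H2-K1 by 1.63 ± 0.11. Of 9 cytokine genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), median 0.83, adjusted p = 0.0174, and adjusted p = 0.0902 with an estimated correlation. Of 27 ribosome biogenesis genes 8 fell and 0 rose (8 and 0 adjusted over the list alone), median -0.25, adjusted p = 0.00552, and adjusted p = 0.0902 with an estimated correlation. Among the transcriptional inhibitors of myogenesis (12) 3 rose and 0 fell (4 and 0 adjusted over the list alone), median 0.37, adjusted p = 0.0177, and adjusted p = 0.0902 with an estimated correlation, Bhlhe40 gaining 1.33 ± 0.15.

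Extracellular matrix genes (39) had 10 higher and 2 lower (15 and 6 adjusted over the list alone) at 0 h with TSA, median 0.16, adjusted p = 0.0171, and adjusted p = 0.160 with an estimated correlation. Timp1 changed by 1.37 ± 0.16 and Tnc by 1.10 ± 0.14. In all 1336 of 7453 probe sets passed (589 higher, 747 lower), 1171 with only the arrays of 0 h in the fit. The count was 798 without TSA replicate 1, 815 without control replicate 2 and 820 without control replicate 1.

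After 4 h in differentiation medium TSA-treated cells had lower sterol synthesis genes and higher Car3 (n = 2 each, a comparison of the first hours of differentiation). Car3, carbonic anhydrase 3, had 5769 ± 1269 against 145 ± 253, log2 change 4.53 ± 0.48, adjusted p = 7.35e-05, and the globin gene Hba-a1 2623 ± 615 against 186 ± 221, log2 change 3.27 ± 0.58, adjusted p = 0.00262. Igfbp3, which binds insulin-like growth factors, had 1176 ± 37.6 against -482 ± 15.2, adjusted p = 5.24e-07, and Chchd10 1754 ± 754 against -134 ± 40.9, adjusted p = 5.00e-04; both were listed at or below 0 on every control array of 4 h. Fst stood at 1393 ± 10.2 against 122 ± 31.7, log2 change 2.56 ± 0.19, adjusted p = 5.74e-06. F3, tissue factor, fell (63.1 ± 36.03 against 1256 ± 3.02, log2 change -2.81 ± 0.20, adjusted p = 4.36e-06), as did Msmo1, a sterol oxidase (246 ± 169 against 1875 ± 37.4, log2 change -2.46 ± 0.28, adjusted p = 1.34e-04). Shmt2, a mitochondrial serine enzyme, had -133 ± 81.1 against 699 ± 27.6, adjusted p = 6.30e-04 and was listed at or below 0 on both TSA arrays. Usp19 had -20.03 ± 90.7 against 715 ± 39.5, adjusted p = 0.0359. The call of Usp19 in TSA against control at 4 h was lost without any 1 of its arrays (adjusted p = 0.0971 and 0.147 without TSA replicates 1 and 2, 0.156 and 0.129 without control replicates 1 and 2), and its other probe set changed by 0.26.

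Of 19 sterol and lipid synthesis genes 0 rose, 15 fell and 4 did not pass (0 and 16 adjusted over the list alone) at 4 h, median -1.06, adjusted p = 1.16e-15. Hmgcs1 changed by -2.15 ± 0.16, Idi1 by -1.91 ± 0.13 and Sqle by -1.37 ± 0.13. Mitosis genes were lower, 20 of 37 falling (26 adjusted over the list alone), median -0.66, adjusted p = 1.50e-13, and adjusted p = 0.0726 with an estimated correlation. Interferon and antigen presentation genes had 3 higher and 0 lower (3 and 0 adjusted over the list alone) of 12, median 0.43, adjusted p = 6.90e-04. The deacetylase inhibitor response had 3 higher and 0 lower (5 and 0 adjusted over the list alone) of 9, median 0.56, adjusted p = 6.90e-04, and adjusted p = 0.0726 with an estimated correlation. Myod1 (0.81 ± 0.11, adjusted p = 3.83e-04), Myf5 (0.92 ± 0.18, adjusted p = 0.00456) and Cdkn1c (1.13 ± 0.21, adjusted p = 0.00413) rose, and Myog did not pass (0.34 ± 0.44, adjusted p = 0.698). In all 846 probe sets passed (418 higher, 428 lower; 431 and 350 after median centring), 105 with only the arrays of 4 h in the fit. The count was 435 without control replicate 1, 473 without control replicate 2 and 522 without TSA replicate 1.

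At 12 h the mitosis list no longer passed with TSA (median 0.11, adjusted p = 0.218), and sterol synthesis was still low (n = 2 each, a comparison at the onset of Myog). Of 19 sterol and lipid synthesis genes 0 rose, 12 fell and 7 did not pass (0 and 15 adjusted over the list alone), median -0.94, adjusted p = 4.30e-20. Mvd, which makes isopentenyl diphosphate, had 424 ± 23.1 against 2009 ± 25.8, log2 change -1.93 ± 0.20, adjusted p = 2.25e-04, and Fdps changed by -1.17 ± 0.13. Car3 stood at 6696 ± 655 against 150.3 ± 126, log2 change 4.64 ± 0.48, adjusted p = 2.25e-04, Pfn2 at 976 ± 24.4 against -88.1 ± 141, log2 change 2.96 ± 0.21, adjusted p = 1.25e-05, and F3 at 94.1 ± 35.8 against 875 ± 25.7, log2 change -2.14 ± 0.20, adjusted p = 1.11e-04. Igfbp3 (1571 ± 538 against -232 ± 194, adjusted p = 2.65e-07) was listed at or below 0 on both control arrays. Targets of p53 (12 measured) had 3 higher and 0 lower (8 and 1 adjusted over the list alone), median 0.43, adjusted p = 2.12e-04, among them Mdm2 (0.85 ± 0.16, adjusted p = 0.00894). Of 18 fatty acid oxidation genes 3 fell and 0 rose (3 and 0 adjusted over the list alone), median -0.24, adjusted p = 8.37e-04, and adjusted p = 0.0992 with an estimated correlation. The carnitine transferase Cpt1a changed by -1.26 ± 0.16 and Acaa2 by -0.76 ± 0.09. Interferon and antigen presentation genes had 3 higher members, median 0.24, adjusted p = 0.0106, and adjusted p = 0.0704 with an estimated correlation.

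Myog was lower with TSA at 12 h (559.9 ± 83.8 against 2208 ± 143, log2 change -1.75 ± 0.44, adjusted p = 0.0412), but the call of Myog in TSA against control at 12 h was lost without any 1 of its arrays (adjusted p = 0.149 and 0.235 without TSA replicates 1 and 2, 0.136 and 0.162 without control replicates 1 and 2). Cdkn1a rose (1.06 ± 0.18, adjusted p = 0.00512), and Cdkn1a in TSA against control at 12 h had adjusted p = 0.0533 without TSA replicate 2. Colq had -326 ± 207 against 1035 ± 645, adjusted p = 0.0151, listed at or below 0 on both TSA arrays. Colq in TSA against control at 12 h lost its call without TSA replicate 1 (adjusted p = 0.0960), TSA replicate 2 (0.103) or control replicate 2 (0.156). In all 304 probe sets passed (191 higher, 113 lower), 6 with only the arrays of 12 h in the fit. Without TSA replicate 2 the count was 111, without TSA replicate 1 140, and without control replicate 2 146.

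At 24 h, when control cells had begun to express muscle genes, TSA-treated cells had lower genes of the stress and amino acid response and higher DNA replication and heat shock genes (n = 2 each). Igf2 had -128 ± 145 against 3027 ± 1202, adjusted p = 5.03e-08 and Cox6a2 -280.4 ± 146 against 1118 ± 2.05, adjusted p = 3.71e-10, both listed at or below 0 on both TSA arrays. Ndrg1, a gene induced by hypoxia and differentiation, fell (289 ± 88.9 against 5910.1 ± 145, log2 change -3.84 ± 0.27, adjusted p = 3.47e-06; its other probe set -3.10). The pseudokinase Trib3 fell too (187 ± 121 against 2898 ± 513, log2 change -3.27 ± 0.39, adjusted p = 2.68e-04). The protease gene Lonp1 had 206 ± 338 against 2845 ± 422, log2 change -3.39 ± 0.53, adjusted p = 0.00206, while its other probe set changed by -0.45. Id2 rose (2151 ± 449 against 216 ± 157, log2 change 2.76 ± 0.25, adjusted p = 4.61e-05) and so did Car3 (2612 ± 3.01 against 166 ± 32.3, log2 change 3.18 ± 0.48, adjusted p = 0.00162). Igfbp3 (1992 ± 131 against -58.9 ± 62.9, adjusted p = 3.36e-08) was listed at or below 0 on both control arrays. Myog did not pass (5369 ± 27.2 against 7919 ± 1002, log2 change -0.54 ± 0.44, adjusted p = 0.594).

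Of 26 sarcomere genes 2 rose, 9 fell and 15 did not pass (3 and 11 adjusted over the list alone) at 24 h, median -0.58, adjusted p = 0.00156, and adjusted p = 0.125 with an estimated correlation. Embryonic myosin Myh3 changed by -1.46 ± 0.14 and Actc1 by -1.51 ± 0.14, whereas Actn3 changed by 1.57 ± 0.15. Muscle metabolic enzymes (13) had 4 lower and 1 higher (6 and 2 adjusted over the list alone), median -0.46, adjusted p = 0.00156, and adjusted p = 0.0780 with an estimated correlation. Muscle creatine kinase Ckm changed by -1.06 ± 0.18, adjusted p = 0.00334. The stress and amino acid list (21) had 12 lower and 3 higher (12 and 4 adjusted over the list alone), median -0.85, adjusted p = 7.07e-06. Ddit3 changed by -3.23 ± 0.34, Vegfa by -1.94 ± 0.23 and Slc3a2 by -0.99 ± 0.11. Of 14 glycolysis genes 6 fell and 0 rose (8 and 0 adjusted over the list alone), median -0.52, adjusted p = 7.07e-06, and adjusted p = 0.0681 with an estimated correlation. Pdk1 changed by -1.71 ± 0.14 and Pfkl by -1.45 ± 0.17. Of 18 fatty acid oxidation genes 4 fell and 0 rose (9 and 0 adjusted over the list alone), median -0.43, adjusted p = 1.56e-04, and adjusted p = 0.0681 with an estimated correlation. DNA replication genes (35) had 9 higher and 1 lower (11 and 1 adjusted over the list alone), median 0.38, adjusted p = 3.22e-04. Mcm4 changed by 0.93 ± 0.19 and Cdc6 by 1.13 ± 0.25 but Rfc4 by -0.88 ± 0.19. Cytosolic heat shock genes (13) had 3 higher and 0 lower (5 and 0 adjusted over the list alone), median 0.41, adjusted p = 1.19e-04. Dnaja1 changed by 1.07 ± 0.14. The mitosis list did not pass (median -0.01, adjusted p = 0.528).

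In all 443 probe sets passed at 24 h (199 higher, 244 lower), 9 with only the arrays of 24 h in the fit. The count was 231 and 278 without control replicates 3 and 2, and 237 and 257 without TSA replicates 3 and 2.

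At 48 h the direction turned: TSA-treated cells had higher levels of mitosis genes and of muscle genes than control cells (n = 2 each, a comparison at the end of the series). Fst had 14206 ± 345 against 512 ± 131, log2 change 4.48 ± 0.19, adjusted p = 2.09e-08. Mb, the oxygen store myoglobin, had 7731 ± 449 against 300.2 ± 63.8, log2 change 4.17 ± 0.28, adjusted p = 1.47e-06. Rrad, a small GTPase of muscle, had 5019.6 ± 118 against 385 ± 40.98, log2 change 3.31 ± 0.20, adjusted p = 5.55e-07. Ckm rose by 2.21 ± 0.18, adjusted p = 4.99e-06, and Cdkn1c by 1.30 ± 0.21, adjusted p = 0.00114. Pagr1a (1632 ± 36.9 against -374 ± 65.5, adjusted p = 6.50e-10) was listed at or below 0 on both control arrays, and its other probe set changed by 0.17. Ephx1, epoxide hydrolase, had -198 ± 150.2 against 2961 ± 577, adjusted p = 7.69e-05 and was listed at or below 0 on both TSA arrays. The actin-binding gene Avil (42.00 ± 34.6 against 1849 ± 122, log2 change -3.48 ± 0.36, adjusted p = 3.99e-05), the secreted lipase inhibitor Angptl4 (-2.97 ± 0.21, adjusted p = 1.75e-06) and Chchd10 (1846 ± 38.3 against 15410.0 ± 1860.5, log2 change -2.97 ± 0.51, adjusted p = 0.00151) fell. Myog (-0.02 ± 0.44, adjusted p = 0.984), Acta1 (0.66 ± 0.27, adjusted p = 0.109) and Igf2 (0.21 ± 0.20, adjusted p = 0.527) did not pass.

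Of 37 mitosis genes 28 rose, 0 fell and 9 did not pass (31 and 0 adjusted over the list alone) at 48 h, median 1.13, adjusted p = 2.12e-18. Cdk1 changed by 2.85 ± 0.17, Anln by 2.11 ± 0.14 and Mki67 by 1.68 ± 0.14. DNA replication genes (35) had 14 higher and 1 lower (14 and 3 adjusted over the list alone), median 0.58, adjusted p = 1.45e-04. Rrm2 changed by 2.02 ± 0.16 and Pcna by 1.12 ± 0.14. Sarcomere genes (26) had 12 higher and 0 lower (15 and 1 adjusted over the list alone), median 0.69, adjusted p = 9.85e-07. Myh3 changed by 1.26 ± 0.14, Mylpf by 1.15 ± 0.14 and Actn3 by 1.60 ± 0.15. Muscle metabolic enzymes (13) had 8 higher and 0 lower (8 and 0 adjusted over the list alone), median 1.07, adjusted p = 7.10e-06. Brain-type creatine kinase Ckb changed by 3.19 ± 0.13. Of 17 excitation-contraction coupling genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), median 0.52, adjusted p = 1.77e-04. The receptor gene Chrnb1 changed by 1.51 ± 0.18 and Ryr1 by 1.13 ± 0.30. The list of follistatin, myostatin and the TGF-beta family (26) had 7 higher and 2 lower (8 and 2 adjusted over the list alone), median 0.43, adjusted p = 0.00535. Sterol and lipid synthesis now had 9 higher and 0 lower (13 and 2 adjusted over the list alone) of 19, median 0.69, adjusted p = 9.53e-06, and adjusted p = 0.0849 with an estimated correlation. Idi1 changed by 1.57 ± 0.13. Ribosome biogenesis (27) had 6 lower and 0 higher (6 and 0 adjusted over the list alone), median -0.30, adjusted p = 0.00704, and adjusted p = 0.134 with an estimated correlation. In all 1464 probe sets passed (786 higher, 678 lower), 21 with only the arrays of 48 h in the fit and 968 without TSA replicate 2.

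Averaged over the 5 times, TSA raised Car3 (3.41 ± 0.22, adjusted p = 3.92e-07), Igfbp3, Pfn2, Fst and Ccn2 and lowered F3 and Cxcl12, each with 10 arrays per side. Fst gained 1.94 ± 0.09, adjusted p = 1.36e-08, and the nephronectin gene Npnt, an integrin ligand, had 2755 ± 977 against 685 ± 336, log2 change 1.83 ± 0.07, adjusted p = 4.48e-09. S100a13, a calcium-binding protein, gained 1.87 ± 0.08, adjusted p = 9.61e-09, and its other probe sets 0.17 and 1.31. F3 changed by -2.08 ± 0.09, adjusted p = 1.04e-08, the chemokine gene Cxcl12 by -1.61 ± 0.08, adjusted p = 2.29e-08, Igfbp6 by -1.26 ± 0.16, adjusted p = 1.26e-04, Tkt by -1.42 ± 0.25, adjusted p = 0.00134 and Comtd1 by -1.14 ± 0.16, adjusted p = 2.28e-04. Myod1 (0.28 ± 0.05, adjusted p = 0.00104), Myf5 (0.42 ± 0.08, adjusted p = 0.00187), Des (0.47 ± 0.08, adjusted p = 9.64e-04) and Cdkn1a (0.50 ± 0.08, adjusted p = 7.34e-04) rose by small amounts, and Myog did not pass (0.01 ± 0.19, adjusted p = 0.986). In the lists that held with both correlations, sterol and lipid synthesis had 12 lower and 0 higher (13 and 0 adjusted over the list alone) of 19, median -0.42, adjusted p = 1.55e-08. The deacetylase inhibitor response had 5 higher and 0 lower (5 and 0 adjusted over the list alone) of 9, median 0.50, adjusted p = 6.89e-05. Interferon and antigen presentation had 4 higher and 0 lower (4 and 0 adjusted over the list alone) of 12, median 0.22, adjusted p = 0.00248. The stress and amino acid response had 12 lower and 3 higher (14 and 4 adjusted over the list alone) of 21, median -0.26, adjusted p = 0.00373. In all 1642 probe sets passed (757 higher, 885 lower), and centring each array on its median turned the split to 835 higher and 729 lower.

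The effect of TSA differed between times for 1658 of 7453 probe sets in a test of the difference itself. The effect at 48 h minus that at 0 h had a median of 2.80 over the mitosis list (36 of 37 members higher, adjusted p = 6.27e-36, and adjusted p = 0.00364 with an estimated correlation), 1.18 over DNA replication (21 of 35, 1.17e-09 and 0.00364), 1.31 over sterol and lipid synthesis (12 of 19, 6.85e-11 and 0.0265) and 0.61 over sarcomere genes (8 of 26, 7.88e-04 and 0.102). These list tests between the ends of the series were chosen after the data were seen. The effect on Kif20a, a mitotic kinesin, changed with time (adjusted p of the change 9.22e-08). Kif20a was lower with TSA at 0 h (219.9 ± 34.4 against 1832 ± 64.9), and at 48 h it stood at 515 ± 74.2 against -92.7 ± 122, where no fold is given since both control arrays were at or below 0. Hcfc1r1 had effects of 1.53 at 0 h and -0.90 at 48 h (adjusted p of the change 3.84e-07).

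**Figure D1:**
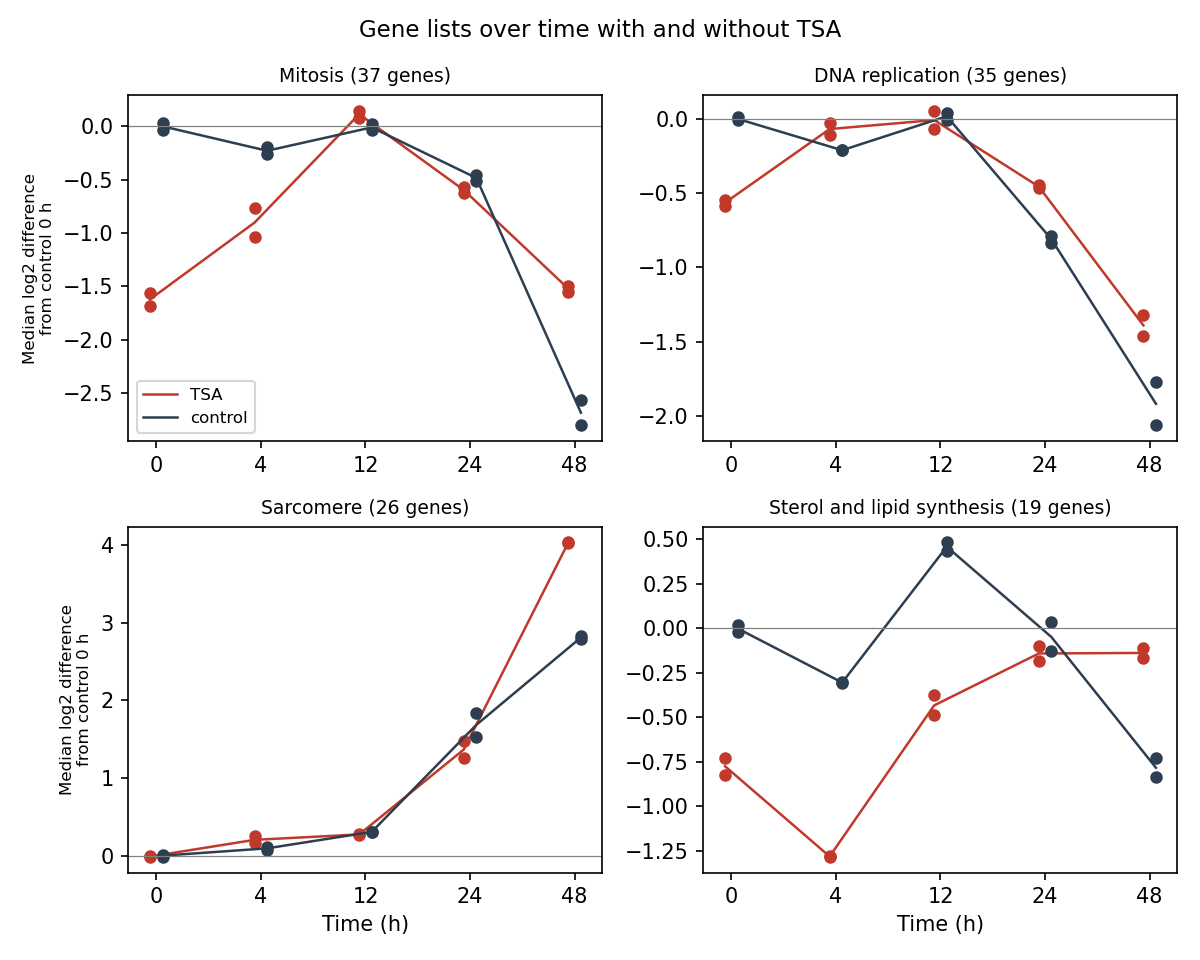
Median log2 difference from control 0 h over the genes of 4 lists (y axis) against time in hours (x axis) in control and TSA-treated cells; points are arrays and lines join group means. The mitosis list of TSA-treated cells starts below the controls at 0 h (median effect -1.62) and ends above them at 48 h (1.13).

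In the second arm, cells with the vector alone also differentiated between 12 and 36 h (n = 3 each), the background against which Sir2 was set. Embryonic myosin Myh3 reached 2106 ± 134 against 100.4 ± 3.12, log2 change 4.27 ± 0.10, adjusted p = 2.13e-10. The embryonic light chain Myl4 had 3008 ± 114 against 83.8 ± 1.11, log2 change 5.02 ± 0.15, adjusted p = 1.70e-09 (its other probe set 0.78). Mb had 1660.0 ± 210.4 against 73.1 ± 19.3, log2 change 4.37 ± 0.32, adjusted p = 1.03e-06. Cox6a2 had 2205 ± 151 against 67.1 ± 13.9, log2 change 4.88 ± 0.31, adjusted p = 3.33e-07, and Csrp3, a muscle LIM protein, 338 ± 54.7 against 8.72 ± 2.07, log2 change 4.30 ± 0.22, adjusted p = 6.38e-08. Trib3 gained 4.31 ± 0.25, adjusted p = 1.46e-07, caveolin 3 (Cav3) 4.08 ± 0.16, adjusted p = 1.35e-08, perinatal myosin Myh8 3.76 ± 0.18, adjusted p = 2.73e-08, Mef2c 2.62 ± 0.31, adjusted p = 4.61e-05 and Cdkn1c 2.69 ± 0.15, adjusted p = 1.04e-07. Mgp, matrix Gla protein, fell (45.8 ± 1.54 against 544 ± 76.8, log2 change -3.33 ± 0.15, adjusted p = 2.18e-08). The water channel Aqp1 (-3.02 ± 0.16, adjusted p = 9.37e-08), the urokinase receptor Plaur (-2.56 ± 0.18, adjusted p = 8.29e-07), the collagen-processing gene Pcolce (-2.37 ± 0.16, adjusted p = 6.85e-07) and Ccnd1 (-1.003 ± 0.11, adjusted p = 1.90e-05) fell too. Csrp3 and Myh8 at 12 h and Aqp1 and Plaur at 36 h had vector means under the pseudocount of 8.82, so their log2 changes are compressed.

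Of 28 sarcomere genes 23 rose, 1 fell and 4 did not pass (24 and 1 adjusted over the list alone) in vector cells, median 2.04, adjusted p = 3.93e-21. Muscle metabolic enzymes had 12 higher and 1 lower (12 and 1 adjusted over the list alone) of 14, median 1.62, adjusted p = 9.42e-10. Excitation-contraction coupling genes had 14 higher and 0 lower (14 and 0 adjusted over the list alone) of 18, median 0.78, adjusted p = 2.35e-09. Of 37 mitosis genes 36 fell and 0 rose (36 and 0 adjusted over the list alone), median -1.38, adjusted p = 6.74e-22. Of 35 DNA replication genes 27 fell and 0 rose (28 and 0 adjusted over the list alone), median -0.86, adjusted p = 2.35e-09. Cdc20 changed by -1.89 ± 0.10 and Mcm5 by -1.24 ± 0.14. Sterol and lipid synthesis had 15 lower and 0 higher (16 and 0 adjusted over the list alone) of 19, median -1.19, adjusted p = 1.35e-10. The stress and amino acid response had 12 higher and 4 lower (12 and 4 adjusted over the list alone) of 21, median 1.27, adjusted p = 6.40e-07. Asns changed by 2.51 ± 0.11. Immediate early genes (17) had 6 higher and 1 lower (6 and 1 adjusted over the list alone), median 0.36, adjusted p = 0.0127, and adjusted p = 0.0521 with an estimated correlation. In all 2389 of 7453 probe sets passed (922 higher, 1467 lower).

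Sirt1, the mouse gene related to the inserted Sir2, was read by 1 probe set. Its intensity was 37.5, 48.7 and 39.9 on the Sir2 arrays of 12 h and 80.5, 69.2 and 35.8 on those of 36 h, against 20.3, 9.48 and 14.2 on the vector arrays of 12 h and 39.4, 19.6 and 36.9 on those of 36 h. Averaged over both times it was higher with Sir2 (log2 change 0.95 ± 0.19, adjusted p = 0.00641). At 12 h the log2 change was 1.14 ± 0.27, adjusted p = 0.0316, and the call of Sirt1 in Sir2 against vector at 12 h was lost without vector replicate b (adjusted p = 0.104), vector replicate c (0.0962) or Sir2 replicates a (0.0702), b (0.109) or c (0.0666). At 36 h it did not pass (0.77 ± 0.27, adjusted p = 0.105), and Sirt1 in Sir2 against vector at 36 h passed without Sir2 replicate c (0.0244). The labels do not give the species of the insert, so the probe set need not read it. In the TSA arm the probe set was too dim to be tested: its values lay between -66.7 and 105 on every array except those of TSA 48 h, which read 199 and 408.

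At 12 h cells with Sir2 had lower contractile genes and higher division genes than vector cells (n = 3 each), a comparison of how Sir2 bears on early differentiation. Acta1 fell (499.6 ± 24.3 against 1576 ± 80.6, log2 change -1.64 ± 0.10, adjusted p = 4.33e-06), and so did Pgam2, muscle phosphoglycerate mutase (4.32 ± 0.357 against 70.7 ± 2.08, log2 change -2.60 ± 0.11, adjusted p = 1.07e-07). The Sir2 mean of Pgam2 at 12 h was under the pseudocount of 8.82, so this log2 change is compressed. Lower too were fast troponin T Tnnt3 (39.4 ± 6.79 against 159.5 ± 11.5, log2 change -1.81 ± 0.13, adjusted p = 1.37e-05) and Fst (16.1 ± 10.4 against 66.96 ± 2.90, log2 change -1.71 ± 0.26, adjusted p = 0.00273). Ccnd1 rose (572 ± 39.3 against 209 ± 10.9, log2 change 1.41 ± 0.11, adjusted p = 1.37e-05), and Cdkn1a fell (-0.61 ± 0.10, adjusted p = 0.00434). Myod1 fell by 0.52 ± 0.11 (adjusted p = 0.0164), and Myod1 in Sir2 against vector at 12 h lost its call without vector replicate a (adjusted p = 0.0652) or Sir2 replicate a (0.0732). Myog fell by 0.88 ± 0.20 (adjusted p = 0.0260), and Myog in Sir2 against vector at 12 h lost its call without vector replicates a (0.0522) or c (0.115) or Sir2 replicates a (0.101) or b (0.106).

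Of 28 sarcomere genes 0 rose, 17 fell and 11 did not pass (0 and 19 adjusted over the list alone) with Sir2 at 12 h, median -0.999, adjusted p = 1.24e-21. Myh3 changed by -1.34 ± 0.10. Muscle metabolic enzymes (14) had 6 lower and 0 higher (8 and 0 adjusted over the list alone), median -0.58, adjusted p = 5.55e-10. Excitation-contraction coupling (18) had 10 lower and 0 higher (12 and 0 adjusted over the list alone), median -0.54, adjusted p = 2.78e-11. Atp2a1 changed by -1.52 ± 0.12 and Ryr1 by -1.27 ± 0.17. Of 12 myogenic factors 4 fell and 0 rose (5 and 0 adjusted over the list alone), median -0.37, adjusted p = 0.00386. Mef2a changed by -0.69 ± 0.13. Cell cycle exit genes (15) had 5 lower and 1 higher (7 and 2 adjusted over the list alone), median -0.30, adjusted p = 0.00812. Gadd45b changed by -0.79 ± 0.14 and Rbl1 by 0.91 ± 0.19. DNA replication genes (35) had 11 higher and 0 lower (17 and 0 adjusted over the list alone), median 0.39, adjusted p = 1.82e-12. Thymidine kinase Tk1 changed by 0.87 ± 0.13, Rfc4 by 0.75 ± 0.10 and Mcm4 by 0.74 ± 0.12. Mitosis genes (37) had 11 higher and 0 lower (23 and 0 adjusted over the list alone), median 0.46, adjusted p = 8.07e-14. Top2a changed by 0.53 ± 0.10. Immediate early genes (17) had 7 higher and 0 lower (8 and 0 adjusted over the list alone), median 0.39, adjusted p = 6.43e-04. Klf4 changed by 0.63 ± 0.11 and Ier3 by 0.73 ± 0.14. Sterol and lipid synthesis (19) had 2 lower and 0 higher (2 and 0 adjusted over the list alone), median -0.18, adjusted p = 0.00221, and adjusted p = 0.0737 with an estimated correlation. Inflammatory cytokines (6) had 2 higher and 0 lower (2 and 0 adjusted over the list alone), median 0.42, adjusted p = 0.00245, and adjusted p = 0.0675 with an estimated correlation.

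In all 414 probe sets passed at 12 h (207 higher, 207 lower), and centring each array on its median turned the split to 124 higher and 215 lower. The count was 215 without vector replicate c, 241 without Sir2 replicate a, 241 without Sir2 replicate b, 243 without the filter on dim probe sets, 208 with only the arrays of 12 h, and 243 without vector replicate b and Sir2 replicate c, which deviated together. The title of that vector array has bb where others have 1 letter, so its reading as replicate b is uncertain.

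At 36 h cells with Sir2 had higher Ephx1 and Plaur and lower Fst than vector cells (n = 3 each, a comparison of the later stage). Fst had 47.2 ± 10.1 against 407 ± 24.4, log2 change -2.91 ± 0.26, adjusted p = 5.94e-05. Ephx1 had 257 ± 25.5 against 21.5 ± 3.65, log2 change 3.13 ± 0.25, adjusted p = 2.49e-05. Plaur had 94.8 ± 12.6 against 8.39 ± 1.75, log2 change 2.59 ± 0.18, adjusted p = 2.49e-05. Aqp1 had 52.5 ± 17.6 against 3.69 ± 0.468, log2 change 2.26 ± 0.16, adjusted p = 2.49e-05, and the keratin gene Krt19 39.4 ± 12.1 against 2.73 ± 1.01, log2 change 2.03 ± 0.16, adjusted p = 2.88e-05. Gpr137b gained 2.02 ± 0.17, adjusted p = 3.67e-05, the histocompatibility gene H2-D4 1.997 ± 0.28, adjusted p = 0.00107, Mgp 1.92 ± 0.15, adjusted p = 2.49e-05 and the kinase gene Prkg2 1.82 ± 0.34, adjusted p = 0.00531. The vector means of Plaur, Aqp1, Krt19 and Prkg2 were under the pseudocount of 8.82, so their log2 changes are compressed. The surface protein gene Cd24a (118 ± 25.6 against 376 ± 69.4, log2 change -1.60 ± 0.16, adjusted p = 1.07e-04), the light chain Myl6b (-1.49 ± 0.15, adjusted p = 9.52e-05), the bone morphogenetic protein antagonist Chrd (-1.43 ± 0.24, adjusted p = 0.00260) and Ndrg4 (-1.36 ± 0.11, adjusted p = 2.49e-05; other probe set -0.65) fell. Zap70 changed by -1.73 ± 0.35, adjusted p = 0.00874, and its other probe set by -0.06. Ccnd1 (1.06 ± 0.11, adjusted p = 1.04e-04) and Myf5 (0.90 ± 0.17, adjusted p = 0.00584) rose. Myh3 fell (-0.98 ± 0.10, adjusted p = 1.56e-04). Myog (-0.36 ± 0.20, adjusted p = 0.317) and Myod1 (-0.33 ± 0.11, adjusted p = 0.0836) did not pass.

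No list that passed at 36 h with the preset correlation passed with an estimated one. Sarcomere genes (28) had 16 lower and 1 higher (22 and 1 adjusted over the list alone), median -0.55, adjusted p = 1.32e-11, and adjusted p = 0.0747 with an estimated correlation. Myh1 changed by -1.35 ± 0.16 and Actn3 by -1.07 ± 0.13. Muscle metabolic enzymes (14) had 8 lower and 0 higher (9 and 1 adjusted over the list alone), median -0.52, adjusted p = 1.83e-05, and adjusted p = 0.0747 with an estimated correlation. Ckb changed by -0.95 ± 0.12. Excitation-contraction coupling (18) had 7 lower and 0 higher (9 and 0 adjusted over the list alone), median -0.43, adjusted p = 4.54e-07, and adjusted p = 0.0747 with an estimated correlation. Atp2a2 changed by -1.04 ± 0.10. Of 37 mitosis genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), median 0.18, adjusted p = 2.31e-05, and adjusted p = 0.0925 with an estimated correlation. Extracellular matrix genes (36) had 13 higher and 1 lower (18 and 3 adjusted over the list alone), median 0.29, adjusted p = 1.63e-05, and adjusted p = 0.104 with an estimated correlation. Decorin (Dcn) gained 1.43 ± 0.14 and the collagen gene Col3a1 0.93 ± 0.12, whereas periostin Postn changed by -1.10 ± 0.12. The insulin-like growth factor axis (10) had 2 higher and 0 lower (5 and 0 adjusted over the list alone), median 0.39, adjusted p = 0.00858, and adjusted p = 0.0876 with an estimated correlation. Igfbp6 changed by 1.19 ± 0.12 and Igfbp2 by 0.57 ± 0.11. Cytosolic heat shock genes (14) had 2 lower and 0 higher (2 and 0 adjusted over the list alone), median -0.21, adjusted p = 0.0140, and adjusted p = 0.205 with an estimated correlation. Interferon and antigen presentation genes (12) had 4 higher and 0 lower (5 and 0 adjusted over the list alone), median 0.21, adjusted p = 0.0300, and adjusted p = 0.117 with an estimated correlation. H2-D1 changed by 0.93 ± 0.10. Without Sir2 replicate c the adjusted p was 0.0571. In all 690 probe sets passed (450 higher, 240 lower; 478 and 154 after median centring), and 458, 422 and 431 without vector replicate a, vector replicate c and Sir2 replicate a.

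Averaged over 12 and 36 h (6 arrays per side), Sir2 cells had higher Ephx1 (2.11 ± 0.18, adjusted p = 1.18e-05), Hmga2, an architectural chromatin protein (1.93 ± 0.17, adjusted p = 2.00e-05), Aqp1 (1.83 ± 0.12, adjusted p = 2.56e-06), Plaur (1.75 ± 0.13, adjusted p = 5.69e-06) and Ccnd1 (1.24 ± 0.07, adjusted p = 2.56e-06). Fst (-2.31 ± 0.19, adjusted p = 1.01e-05), Pgam2 (-1.70 ± 0.07, adjusted p = 2.74e-07), the myosin gene Myh1 (-1.53 ± 0.11, adjusted p = 5.69e-06), Mb (-1.44 ± 0.23, adjusted p = 0.00122) and the adhesion receptor Adgrg1 (-1.31 ± 0.09, adjusted p = 4.95e-06) were lower. Myod1 (-0.42 ± 0.08, adjusted p = 0.00336), Myog (-0.62 ± 0.14, adjusted p = 0.0148), Igf2 (-0.66 ± 0.13, adjusted p = 0.00637) and Cdkn1c (-0.52 ± 0.11, adjusted p = 0.00646) fell. Of 28 sarcomere genes 0 rose, 19 fell and 9 did not pass (1 and 22 adjusted over the list alone), median -0.74, adjusted p = 1.16e-19. Muscle metabolic enzymes had 9 lower and 0 higher (11 and 0 adjusted over the list alone) of 14, median -0.44, adjusted p = 1.54e-09. Excitation-contraction coupling genes had 11 lower and 0 higher (14 and 0 adjusted over the list alone) of 18, median -0.49, adjusted p = 2.54e-11. Mitosis genes had 21 higher and 0 lower (28 and 0 adjusted over the list alone) of 37, median 0.34, adjusted p = 2.76e-12. DNA replication genes had 5 higher and 0 lower (5 and 0 adjusted over the list alone) of 35, median 0.19, adjusted p = 4.58e-04. The extracellular matrix list had 13 higher and 1 lower (15 and 3 adjusted over the list alone) of 36, median 0.16, adjusted p = 9.54e-05, and adjusted p = 0.0974 with an estimated correlation. Myogenic factors had 6 lower and 1 higher (8 and 2 adjusted over the list alone) of 12, median -0.41, adjusted p = 0.00892, and adjusted p = 0.0767 with an estimated correlation. In all 937 probe sets passed (558 higher, 379 lower).

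The effect of Sir2 changed between 12 and 36 h for 131 probe sets (95 with a higher effect at 36 h and 36 with a lower one, 120 and 21 after median centring). Pgam2 had effects of -2.60 at 12 h and -0.79 at 36 h (adjusted p of the change 3.70e-04), the first of which is compressed. Acta1 had effects of -1.64 and -0.39 (0.00254) and Actc1 -2.12 and -0.42 (0.00130). Cmbl, a hydrolase, went from -0.58 to 1.19 and the microfibril gene Mfap4 from 0.82 to -0.93 (both 0.00130). Over the DNA replication list the effect was lower at 36 h, with 7 lower and 0 higher (13 and 0 adjusted over the list alone) of 35, median -0.44, adjusted p = 1.07e-10. Sarcomere genes had 7 higher and 1 lower (11 and 1 adjusted over the list alone) of 28, median 0.31, adjusted p = 4.29e-04, and adjusted p = 0.236 with an estimated correlation. The count was 32 without vector 12 h replicate b and Sir2 12 h replicate c together, 46 without the filter, 57 with replicate letters as a block and 207 with trend and robust variance estimation. Leaving out 1 array gave 61, 80 and 65 without vector 12 h replicates a, b and c, and 52, 45 and 113 without Sir2 12 h replicates a, b and c. It gave 66, 72 and 55 without vector 36 h replicates a, b and c, and 55, 58 and 63 without Sir2 36 h replicates a, b and c.

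**Figure D2:**
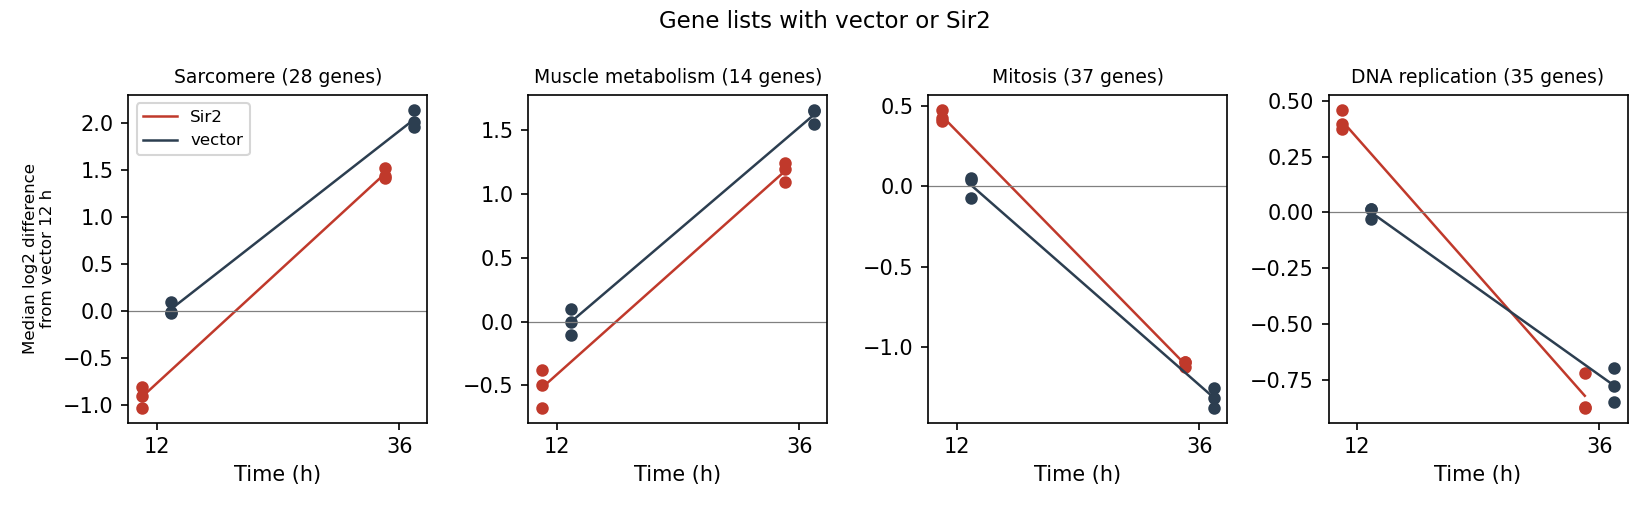
Median log2 difference from vector 12 h over the genes of 4 lists (y axis) against time in hours (x axis) in vector and Sir2 cells; points are arrays and lines join group means. The sarcomere list lies lower with Sir2 at both times (median effect -0.999 at 12 h and -0.55 at 36 h, where the call was lost with an estimated correlation, adjusted p = 0.0747).

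Fst changed in both arms in opposite directions. With TSA it was higher at 0 h (438 ± 7.67 against 59.9 ± 10.2), 4 h (1393 ± 10.2 against 122 ± 31.7) and 48 h (14206 ± 345 against 512 ± 131; n = 2 each). At 12 h (0.67 ± 0.19, adjusted p = 0.0808) and 24 h (0.45 ± 0.19, adjusted p = 0.226) it did not pass, and Fst in TSA against control at 12 h passed without control replicate 2 (adjusted p = 0.0316). With Sir2 it was lower at 12 h (16.1 ± 10.4 against 66.96 ± 2.90) and at 36 h (47.2 ± 10.1 against 407 ± 24.4; n = 3 each). Without treatment it rose in the control series from 0 to 48 h (log2 change 1.70 ± 0.19, adjusted p = 1.95e-05) and in vector cells from 12 to 36 h (2.45 ± 0.26, adjusted p = 2.33e-05).

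**Figure D3:**
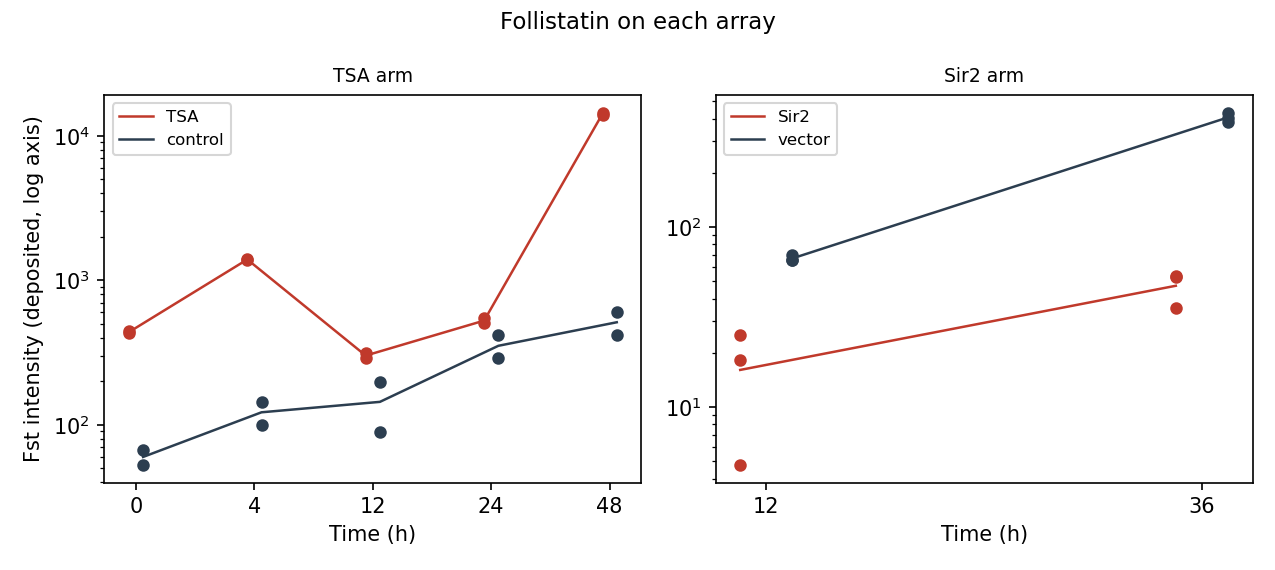
Deposited intensity of Fst on each array (y axis, log scale) against time in hours (x axis) in the TSA arm and in the Sir2 arm; points are arrays and lines join group means. The arrays of TSA at 48 h, with a mean of 14206, lie above the control arrays, and those of Sir2 lie below the vector arrays at 36 h.

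Gene lists drawn from one arm were tested in the other, where no array is shared. Of 308 genes lowered by Sir2 on average, 108 rose and 8 fell, median 0.39, adjusted p = 2.09e-13 in TSA against control at 48 h. This list did not pass at 0 h (adjusted p = 0.150), 4 h (0.419), 12 h (0.440) or 24 h (0.947). Genes raised by TSA on average did not pass as a list for the Sir2 mean (0.959) or with Sir2 at 12 h (0.439) or 36 h (0.542). Genes lowered by TSA on average (727) had 111 higher and 31 lower for the Sir2 mean (median 0.08, adjusted p = 1.82e-04). With Sir2 at 36 h this list had 81 higher and 13 lower (median 0.10, adjusted p = 1.10e-04). At 12 h it had 42 higher and 23 lower (median 0.06, adjusted p = 0.0452, and adjusted p = 0.0517 with an estimated correlation). Of 934 genes that rose in control cells from 0 to 48 h, 103 fell and 17 rose, median -0.08, adjusted p = 1.71e-07 with Sir2 at 12 h, and 78 rose and 72 fell, median -0.03, adjusted p = 0.542 at 36 h. The effect of Sir2 on these genes was higher at 36 h than at 12 h (38 higher and 3 lower, median 0.10, adjusted p = 1.11e-04). Of 1136 genes that fell in control cells, 99 rose and 7 fell, median 0.13, adjusted p = 1.42e-10 with Sir2 at 12 h. Of 707 genes that rose in vector cells from 12 to 36 h, 115 rose and 36 fell, median 0.11, adjusted p = 0.00232 with TSA at 0 h. At 4 h this list had 75 higher and 27 lower, median 0.02, adjusted p = 0.0404, and at 24 h it had 90 lower and 18 higher, median -0.15, adjusted p = 9.91e-06. It did not pass at 12 h (adjusted p = 0.440) or 48 h (0.398). Of 1153 genes that fell in vector cells, 264 fell and 106 rose, median -0.18, adjusted p = 6.61e-05 with TSA at 0 h. At 4 h this list had 166 lower and 85 higher, median -0.11, adjusted p = 0.0404. It moved the opposite way at 24 h, with 81 higher and 32 lower, median 0.09, adjusted p = 6.61e-04, and at 48 h, with 227 higher and 117 lower, median 0.08, adjusted p = 0.0282. At 12 h it did not pass (adjusted p = 0.440).

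The adipocyte (3 genes, adjusted p = 0.543 for the TSA mean and 0.0908 for the Sir2 mean), bone and cartilage (0.916 and 0.274), leukocyte (4 genes, 0.618 and 0.660), endothelial (0.916 and 0.566), neuronal (0.553 and 0.301) and smooth muscle lists (5 genes, 0.0883 and 0.0577) did not pass for either mean. Single members did pass: Uchl1, a neuronal ubiquitin hydrolase, rose with TSA (1.42 ± 0.17, adjusted p = 6.34e-05 for the mean), as did Tagln, an actin-binding gene of smooth muscle (1.05 ± 0.09, adjusted p = 4.79e-06). At single times the neuronal list passed with Sir2 at 12 h (median 0.21, adjusted p = 0.0140, and adjusted p = 0.103 with an estimated correlation). The smooth muscle list passed with TSA at 24 h (median 0.49, adjusted p = 0.0367, and adjusted p = 0.125 with an estimated correlation) and with Sir2 at 36 h (median -0.55, adjusted p = 0.0263, and adjusted p = 0.124 with an estimated correlation). Leaving out 1 array ended each of these calls (the weakest adjusted p was 0.0564 without Sir2 12 h replicate c, 0.269 without TSA 24 h replicate 2 and 0.0571 without Sir2 36 h replicate c). Deacetylase genes themselves (7 and 8 measured) did not pass as a group for either mean (adjusted p = 0.835 and 0.566). The 34 genes of oxidative phosphorylation did not pass for the TSA mean (median 0.05, adjusted p = 0.543) but were lower with TSA at 12 h (median -0.15, adjusted p = 0.0431, and adjusted p = 0.355 with an estimated correlation). In the Sir2 arm 33 were measured, and the list was lower for the mean (median -0.08, adjusted p = 0.0467, and adjusted p = 0.408 with an estimated correlation) and at 36 h (median -0.15, adjusted p = 0.0126, and adjusted p = 0.397 with an estimated correlation), with 0 single genes past the threshold. Leaving out 1 array ended each of these calls as well (the weakest adjusted p was 0.210 without control 12 h replicate 1, 0.116 without vector 12 h replicate a and 0.0777 without Sir2 36 h replicate b). Median centring ended those of TSA at 12 h (adjusted p = 0.0844) and of the Sir2 mean (0.0593), and quantile normalization that of the Sir2 mean (0.0819).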

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

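The tests of scaling, the tests of delayed differentiation, the list tests of DNA replication within treated cells and the list tests between the ends of the TSA series were chosen only after the results they measure were seen, and the bound for the DNA replication test at 24 h was rewritten after its value was seen. The split by title suffix and the fit without both deviating arrays were added after the data were seen, with their bounds set before their own values were. The tests of Fst against other genes and of exchanged labels were chosen before their results were seen, but how the Fst test is read was changed after its values were seen.

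The effect of TSA differed between times for 1658 probe sets, and that of Sir2 for 131. Among the 5 genes of smallest p, the largest difference between any times in the TSA effect on Hcfc1r1 was 2.79 (adjusted p = 3.84e-07). For Kif20a (4.70, 9.22e-08), Pagr1a (3.88, 4.09e-08), Cox6a2 (3.19, 4.09e-08) and slow myosin Myh7 (3.19, 9.22e-08) a compared group was at or below 0 on every array, so these are not folds and p can be too small. The Sir2 effect at 36 h minus that at 12 h was 1.81 for Pgam2 (3.70e-04; compressed, since Pgam2 was under the pseudocount in Sir2 cells at 12 h), -1.75 for Mfap4 (0.00130), 1.77 for Cmbl (0.00130), 1.69 for Actc1 (0.00130) and 1.25 for Acta1 (0.00254). Over lists, the TSA effect at 48 h minus that at 0 h had a median of 1.18 for DNA replication, 2.80 for mitosis and 1.31 for sterol and lipid synthesis, and the Sir2 effect at 36 h minus that at 12 h one of -0.44 for DNA replication.

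Mitosis genes were lower with TSA at 0 h and higher at 48 h. Arrays with the suffix b in the title were in both treatments at 48 h, and the smaller of the medians within arrays with and without b was 1.02, which argues against that suffix as the source. Under quantile normalization and median centring the smallest size of the median at 0 h and 48 h was 1.15, which argues against scaling. As a hypothesis, treated cells could have left the cycle early and returned to it in differentiation medium. A return to the whole cycle should also raise DNA replication genes, and their median in treated cells at 24 h against treated cells at 0 h was 0.143 with a standard deviation of 0.45 over its genes (adjusted p = 0.214), so a return at 24 h stays open. At 48 h against the same 0 h their median was -0.681 with a standard deviation of 0.50 (adjusted p = 6.62e-07), not a rise. The mitosis list did not pass (0.16, adjusted p = 0.300). A return from a later low point, or incomplete exit, stays open.

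Contractile genes were lower with Sir2, although the call of the sarcomere list at 36 h was lost with an estimated correlation (adjusted p = 0.0747). Without vector replicate b and Sir2 replicate c of 12 h, which deviate together, the sarcomere median at 12 h was -1.04, and under 2 other scalings the median nearest 0 at 12 h and 36 h was -0.499, which argue against those arrays and against scaling as the source. A delay of differentiation could lower all genes that rise in untreated cells. Those higher in control 48 h than 0 h were lower with Sir2 at 12 h (adjusted p = 2.76e-04 with an estimated correlation). Contractile genes that rose in control cells were not taken out of that list. The test therefore cannot tell a delay from a fall of contractile genes alone. At 36 h the same test gave 0.469. Of 1136 genes lower in control 48 h than 0 h, 129 were higher and 26 lower with Sir2 at 36 h (median 0.06, adjusted p = 0.00125, and 0.0776 with an estimated correlation), which goes against a full catch-up but rests on the preset correlation. This leaves open whether there was a delay and whether the cells had caught up.

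Fst was higher with TSA at 48 h and lower with Sir2 at 36 h. If Fst had moved only with muscle genes, its effect should lie among theirs. The central 95% of the effects of TSA at 48 h over the 706 other genes higher in vector 36 h than 12 h ended at 1.64, and the highest was 4.17, for Mb, against 4.48 for Fst. The central 95% of the effects of Sir2 at 36 h over the 933 other genes higher in control 48 h than 0 h began at -0.754, and the lowest was -1.49, against -2.91 for Fst. These lists did not pass (adjusted p = 0.398 and 0.542), so they cannot show a shared shift. Mb neared Fst with TSA, so sharing stays open. Under 2 other scalings the smallest size of the effect on Fst was 2.86, which argues against scaling as the source.

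Labels were also exchanged between arrays, within times for the treatments and between times for the vector cells. The real split gave more calls than any other for the TSA mean (1642 against at most 971, in 1 of 100 splits) and for the Sir2 mean (937 against at most 180, in 1 of 100). With 10 splits each there were too few for a share under 0.05 for Sir2 at 12 h (414, highest other 3), Sir2 at 36 h (690, highest other 1) and vector 36 h against 12 h (2389, highest other 0). For the change of the Sir2 effect with time, 3 of 100 splits gave 131 calls or more, the others 153 and 176; these splits keep part of the mean effect of Sir2.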

How the results depend on the processing

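The pseudocounts other than the 40th percentile in the TSA arm, the fits without both deviating arrays and the fits without probe sets at or below 0 were chosen only after the results were seen. The cause of a move was not tested except where the construction of a fit shows it. Of the settings other than leaving out 1 array, 178 summary results kept their call or count within 1.5 times. Beyond these, 22 counts moved further, 4 calls weakened and 2 strengthened. A change of direction was not scored for summary results. Among calls of named genes 122 weakened and 22 strengthened under these settings, and 168 weakened and 7 strengthened when 1 array was left out. With only the groups compared in the fit, which leaves fewer residual degrees of freedom, 105, 6, 9 and 21 probe sets passed for TSA at 4, 12, 24 and 48 h. There were 1536 for control 48 h against 0 h and 208 for Sir2 at 12 h. With no filter, Sir2 at 12 h gave 243 and the Sir2 effect by time 46. Trend and robust estimation gave 207 by time. Without both deviating arrays, Sir2 at 12 h gave 243 and the effect by time 32. Arrays with the same replicate number did not deviate together throughout (correlation over 0.1 in 2 of 5 pairs of the TSA arm and 4 of 18 of the Sir2 arm), so the numbers were taken not to pair the samples. With the replicate block 57 passed in the Sir2 effect by time, and no other count moved over 1.5 times. The planned 5th percentile pseudocount was not run in the TSA arm, where it is negative, and the planned 40th became the one used there.

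With an estimated correlation, the number of lists that passed went from 10 to 3 for TSA at 0 h, 7 to 2 at 4 h, 8 to 2 at 12 h, 8 to 3 at 24 h and 10 to 4 for the TSA mean. It went from 11 to 6 for control 48 h against 0 h. In the Sir2 arm it went from 12 to 5 for the mean, 13 to 8 at 12 h, 10 to 0 at 36 h and 10 to 1 for the Sir2 effect by time. For lists from the other arm, the genes lower in the TSA mean went from 0.0452 to 0.0517 in Sir2 at 12 h and from 0.0412 to 0.0546 in the Sir2 effect by time. Those lower in control 48 h went from 0.00125 to 0.0776 in Sir2 at 36 h and from 0.0436 to 0.203 in the effect by time. Those higher in the Sir2 mean went from 0.0609 to 0.0216 in TSA at 12 h and from 0.0575 to 0.0195 at 48 h. Leaving out 1 array gave 798 to 913 for TSA at 0 h, 435 to 584 at 4 h, 111 to 264 at 12 h, 231 to 278 at 24 h and 968 to 1221 at 48 h. It gave 215 to 331 for Sir2 at 12 h, 422 to 498 at 36 h and 45 to 113 for the effect by time.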

Other observations

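Untreated cells changed stepwise before 48 h (n = 2 each against 0 h). At 4 h the inhibitors Id3 (-2.68 ± 0.34, adjusted p = 0.00266) and Id1 (-1.55 ± 0.25, adjusted p = 0.00899) had fallen, and sterol and lipid synthesis was lower as a list (median -0.31, adjusted p = 1.16e-05, and adjusted p = 0.179 with an estimated correlation). By 12 h Myog had risen (3.48 ± 0.44, adjusted p = 0.00144), and sterol and lipid synthesis was higher, with 7 of 19 genes rising, median 0.44, adjusted p = 1.95e-08, and adjusted p = 0.0536 with an estimated correlation. Sarcomere genes had begun to rise (9 of 26, median 0.30, adjusted p = 5.66e-06, and adjusted p = 0.0536 with an estimated correlation), and oxidative stress genes fell (6 of 21, median -0.55, adjusted p = 3.50e-05, and adjusted p = 0.0536 with an estimated correlation). At 24 h Myog stood 5.25 ± 0.44 above 0 h (adjusted p = 7.21e-06). Sarcomere (16 of 26 rose, median 1.63, adjusted p = 5.84e-19), cell cycle exit (6 of 17 rose, median 0.44, adjusted p = 3.34e-04) and stress and amino acid genes (12 of 21 rose, median 1.10, adjusted p = 4.58e-09) were higher. DNA replication genes (20 of 35 fell, median -0.84, adjusted p = 1.06e-12) were lower.

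TSA-treated cells were also compared with their own 0 h, by list tests chosen only after the results were seen. At 24 h mitosis genes had risen (34 of 37, median 1.08, adjusted p = 3.33e-22), as had sarcomere (15 of 26, median 1.29, adjusted p = 5.31e-13) and sterol and lipid synthesis genes (13 of 19, median 0.74, adjusted p = 4.85e-09). At 48 h sarcomere genes (21 of 26 rose, median 3.87, adjusted p = 4.01e-23) and excitation-contraction coupling genes (14 of 17 rose, median 2.14, adjusted p = 2.96e-12) were higher and DNA replication genes lower (20 of 35 fell, median -0.68, adjusted p = 6.62e-07), while the mitosis list did not pass (median 0.16, adjusted p = 0.300).

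Several further values bear on what was left open. Fst at 48 h differed by 4.71 within arrays whose title has the suffix b and by 4.25 within those without it, and the mitosis median by 1.17 and 1.02. Neither subset alone carried the pattern, though each holds only 1 array per treatment. This split was chosen only after the results were seen. The genes lower with Sir2 on average were higher with TSA at 48 h but moved little over the TSA mean (median 0.08, adjusted p = 7.17e-05).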
